A study of Homo sapiens with 3 samples.

How the data were processed

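The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) for trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, in GIST-T1, an established cell line from a gastrointestinal stromal tumour (GIST). There was 1 untreated library and 1 library from cells given 5-aza-2′-deoxycytidine, an inhibitor of DNA methyltransferases, at 2 µM for 72 hours and then 4-phenylbutyric acid, an inhibitor of histone deacetylases, at 3 mM for a further 48 hours, with drug and medium renewed every 24 hours. Per the labels' protocols, sonicated chromatin was precipitated with an H3K4me3 antibody, ligated to adapters, amplified by PCR and prepared for the SOLiD platform. An input DNA library of untreated cells belongs to the series and was not used here, and there is none of treated cells. Groups were taken from the treatment label of each library.

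Per the submitters' processing notes, reads were aligned with Bowtie2 to hg38 and peaks were called with MACS2. Versions, thresholds, duplicate handling, the treatment of reads with several alignments and the control used for peak calling are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called on each library by itself and not on pooled samples. For each peak the authors' lists give the start, the end and the summit position, the fold enrichment at the summit (a ratio to the local background), the −log10 p-value, the −log10 q-value and a score, which is the −log10 q-value on a larger scale truncated to a whole number. These values are the peak caller's own. Apart from the recovery of summit pileups from fold and p, these values were used only to describe, rank or filter peaks within a list. The highest q was 0.0485 in the untreated list and 0.0466 in the treated list.

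The lists carry no read counts, but the peak caller's fold is (summit pileup + 1) / (background + 1) and its p-value is a Poisson tail of the same pileup and background. A search over whole pileups returned 1 pileup and 1 background per peak, with a tolerance of 0.01 on −log10 p, for 100% of the peaks of both lists. The pileup is the number of extended reads over the summit. The commonest background was 0.741 reads in the untreated list and 0.524 in the treated list, and the shortest peaks were 168 and 171 bp. Since that background is reads times fragment length over genome size, the treated library held 0.695 of the reads of the untreated library. The step by which raised local backgrounds increased, 1 scaled control read, gave the same ratio of 0.695. This second estimate assumes that both lists were called against the same control. Pileups are given in reads of their own library, and their ratio over shared peaks is given both as it stands and per read, divided by this read ratio. For this summit ratio each untreated peak was set against the highest summit among the treated peaks that overlapped it. Untreated peaks under 1 treated peak share its summit, which can raise the ratio and the minimum pileups built on it.

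Peaks were compared on the assembled chromosomes. A peak was shared if it overlapped a peak of the other list by at least 1 bp, counted with numpy 2.4.6 and again with bedtools 2.31.1, which gave the same counts. Regions are peaks of a list merged across gaps of up to 1 kb, and the regions described by summit pileup were merged across gaps of up to 5 kb. A treated-only peak was called isolated if no untreated peak lay within 5 kb. Genes came from the RefSeq table of GRCh38.p14, whose main chromosomes have the coordinates of hg38. That table gives gene starts and ends but neither strand nor transcripts, so the planned windows of 1 kb around transcription starts could not be built. Windows of 1 kb around both annotated ends of each gene were used in their place, for 19974 protein-coding genes on chromosomes 1 to 22 and X. A gene is treated-only where a treated and no untreated peak overlaps its end windows, and untreated-only the other way round. A peak at the end where transcription stops counts like a peak at the start, and starts inside a gene are missed. Coordinates are given on hg38, counted from 1.

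The study has 1 library per group. The treatment was not tested at any gene or across genes, no p-value is given for it, and a difference between the lists is a difference between these libraries. Shares carry Wilson 95% intervals and pileups exact Poisson 95% intervals. Both cover counting error only, not variation between cultures or between immunoprecipitations, and PCR copies without molecular identifiers are not independent molecules. For 25 gene lists fixed before the data were examined, the number of treated-only genes was set against 10000 random lists of the same size, drawn from the coding genes with no untreated peak at their ends (eligible genes), and is given as a percentile that describes these libraries. The share of a list marked in the untreated library was set against random lists drawn from all 19974 coding genes. Matching on promoter CpG content needs a genome, which was not used here, so random lists were unmatched. The lists cover housekeeping genes, genes of GIST and the interstitial cells of Cajal, cancer-testis antigens, germ-cell genes, interferon response, antigen presentation, cytokines, cell cycle inhibitors, genes often methylated in tumours, smooth muscle, neuronal, epithelial, blood cell, endothelial and pluripotency genes, HOX genes, other developmental transcription factors, imprinted genes, chromatin enzymes, the unfolded protein response, genes of liver, pancreas and eye, olfactory receptors, core histones, ZNF zinc finger genes and ribosomal proteins. By symbol or older symbol 99.8% of the listed genes were matched.

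Genes are named by a rule fixed before the data were examined: the 15 treated-only and the 8 untreated-only coding genes with the highest fold, the 3 genes with the highest fold in each list, up to 4 treated-only members of each gene list by fold and up to 2 untreated-only members, KIT, PDGFRA, ANO1 and ETV1 in any state, and the 3 treated-only peaks away from gene ends with the highest fold. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Alternatives fixed before the data were examined were stricter q and fold thresholds, lists of equal length, other overlap rules, other windows, summits in place of whole peaks and all annotated genes. Alternatives added after seeing the data were a distance of more than 5 kb from the other list, a minimum summit pileup, peaks tied to 1 coding gene, genes with no untreated peak anywhere inside them, and random lists matched on gene length and neighbours. A treated pileup of 25 reads was taken as the minimum at which a site scaled down by the median summit ratio would have 7 or more untreated reads in 99% of Poisson draws. The steps were tested on simulated data: 100% of 2000 simulated summits in each list gave back their pileup, and 200 of 200 planted private peaks were found in each list, with 0 others called. Calculations used python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.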

Results

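H3K4me3 peaks were compared between untreated GIST-T1 cells and GIST-T1 cells treated with 5-aza-2′-deoxycytidine and then 4-phenylbutyric acid, with 1 library in each group and no replicates. The series asks how epigenetic inhibitors act on the epigenome of gastrointestinal stromal tumour cells. The untreated list held 26717 peaks, of which 26682 lay on assembled chromosomes and covered 14.5 Mb. The treated list held 36876 peaks, of which 36769 lay on these chromosomes and covered 23.4 Mb. The median peak was 430 bp wide with a summit of 19 reads in the untreated list, and 494 bp wide with a summit of 22 reads in the treated list. The median fold over background, the authors' value, was 10.3 within the untreated list and 13.8 within the treated list. The treated library held fewer reads, 0.695 of those of the untreated library.

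Peaks present in both libraries were higher and wider after treatment. At 12907 shared peaks with an untreated summit of at least 20 reads, the highest overlapping treated summit was a median 1.70 times the untreated one (5th percentile 1.19), although the treated library had fewer reads. This pairing can raise the ratio where 1 treated peak spans several untreated ones. At ETV1, untreated summits of 28, 32 and 41 reads were all set against 1 treated summit of 60. Per read the median ratio was 2.44 (interquartile range 2.13 to 2.82), and it lay above 1 at 99.9% of these peaks. Among 14220 regions that matched 1 to 1, the median width was 1068 bp untreated and 1624 bp treated, and 96.5% were wider in the treated list. The coding genes with the highest fold in the untreated list were CALM3, a calmodulin gene, with a summit of 187 reads, KMT2E, a relative of the H3K4 methyltransferases, with 111 reads, and UBE2T, a ubiquitin-conjugating enzyme, with 112 reads. Their treated summits held 250, 156 and 157 reads. Those with the highest fold in the treated list were SMN2 with 228 reads against 134 untreated, CALM3, and ATG7, an autophagy gene, with 172 against 80. SMN2 has a near-identical copy, SMN1, so its reads cannot be assigned with certainty. The higher summits were found at nearly all shared peaks and are a property of the treated library as a whole, so they accompany every gene group described here. With 1 immunoprecipitation per group, a general drug response and a more efficient immunoprecipitation are not separated by these lists.

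**Figure D1:**
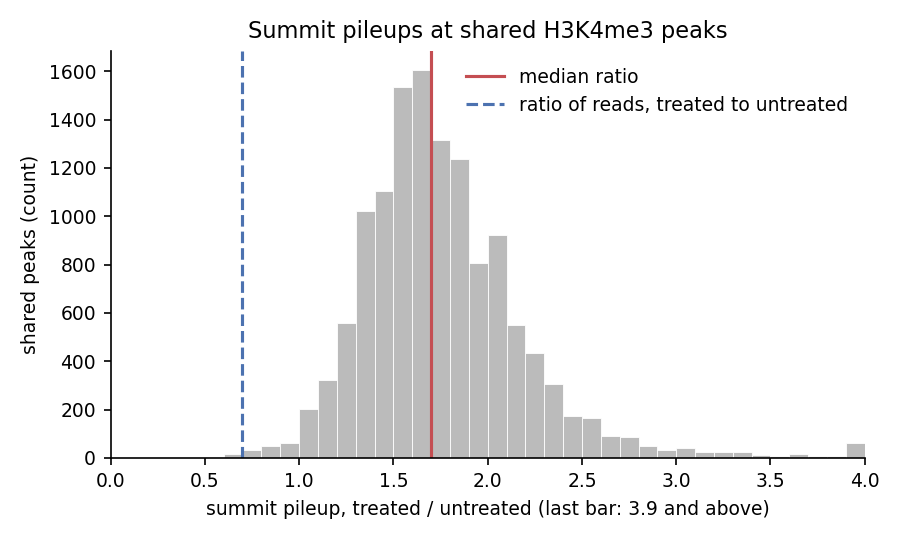
Histogram of the highest overlapping summit pileup of the treated library divided by the summit pileup of the untreated peak (x axis, no unit) at 12907 shared peaks with an untreated summit of at least 20 reads (y axis, number of peaks). The solid line marks the median of 1.70 and the dashed line the ratio of the libraries' reads, 0.695; nearly all peaks lie to the right of the dashed line.

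Nearly every untreated peak was kept, and many weak peaks were added. Of the 26682 untreated peaks, 26353 (98.8%, 95% interval 98.6 to 98.9) overlapped a treated peak and 329 (1.23%, 1.11 to 1.37) did not. Of the 36769 treated peaks, 13374 (36.4%, 35.9 to 36.9) overlapped no untreated peak. The treated-only peaks were narrower than the shared ones, with a median of 245 against 712 bp, and had a median summit of 9 against 38 reads. Of the treated-only peaks 5281 (39.5%) lay within 1 kb of an untreated peak and so extended a marked region, and 6727 (50.3%) lay more than 5 kb from any. The densest cluster, 97 treated-only peaks in 96.9 kb without a coding gene, lay where 79.4% of the peaks had a raised local background. The isolated peaks had a median summit of 9 reads, and 199 of them reached 20 reads. Merged across gaps of up to 5 kb, treated regions with a summit of 10 to 14 reads had no untreated peak nearby in 68.6% of cases (66.7 to 70.4). This share was 11.4% (9.65 to 13.3) for summits of 20 to 24 reads and 0.0506% (0.0197 to 0.130) for summits of 40 reads or more. With both lists reduced to the strongest 26682 peaks, the treated-only peaks numbered 4357 and the untreated-only peaks 1303.

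**Figure D2:**
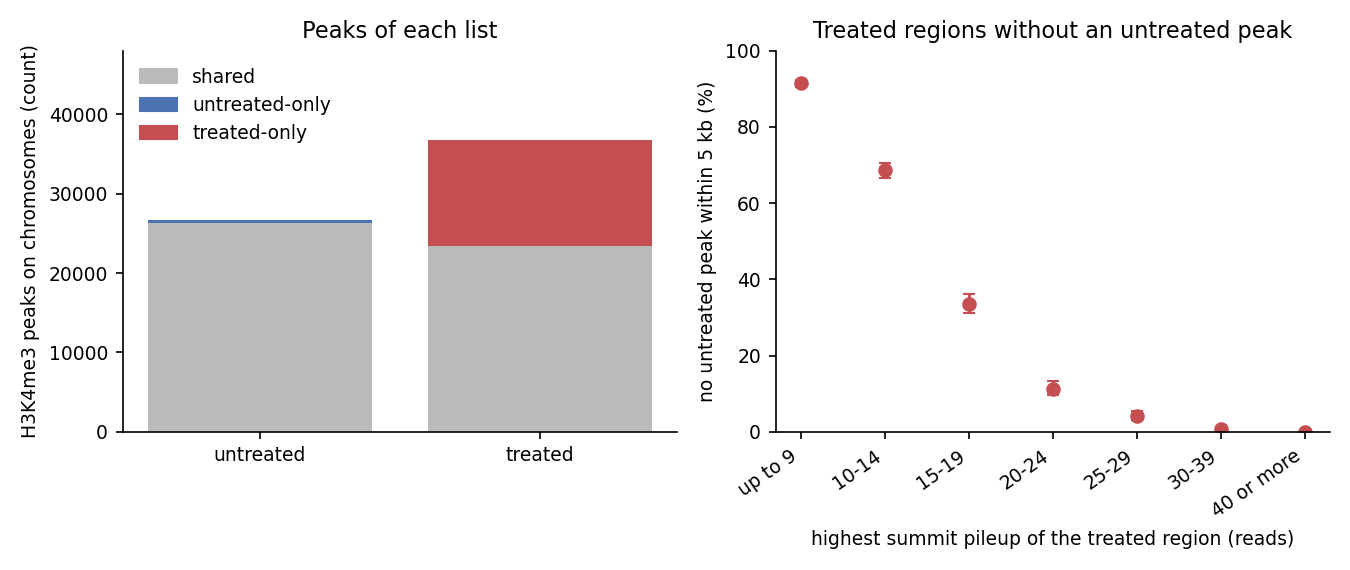
Left, number of H3K4me3 peaks on the chromosomes in each list, split into peaks that overlap a peak of the other list (grey) and peaks that do not (coloured). Right, share of treated regions with no untreated peak within 5 kb (y axis, percent, with Wilson 95% intervals) by the highest summit pileup of the region (x axis, reads), which falls from 91.5% at summits of up to 9 reads to 0.0506% at 40 or more.

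Added peaks, like the untreated-only ones, lay away from gene ends more often than shared ones. Peaks overlapping the 1 kb windows at annotated gene ends made up 73.9% (73.4 to 74.5) of the untreated list and 65.2% (64.7 to 65.7) of the treated list. The share was 76.9% (76.4 to 77.5) among treated peaks shared with the untreated list, 44.6% (43.8 to 45.5) among treated-only peaks and 29.9% (28.8 to 31.0) among isolated treated-only peaks. Of the isolated peaks 41.3% lay inside genes and 28.7% between genes. Untreated-only peaks lay at gene ends in 26.7% of cases (22.3 to 31.8), below the treated-only peaks. Between genes lay 25.8% of the untreated-only and 18.4% of the treated-only peaks, so this position is not particular to peaks added on treatment. In lists of equal length the treated share at gene ends was 75.7%, above the untreated share. The 3 treated-only peaks away from gene ends with the highest fold lay inside CCM2L (chromosome 20, 32019489 to 32019836, 38 reads), DENND1C (chromosome 19, 6475975 to 6476661, 32 reads) and CNKSR3 (chromosome 6, 154508772 to 154509538, 31 reads). The CCM2L and DENND1C peaks lay 67654 and 15110 bp from the nearest untreated peak, and the CNKSR3 peak 211 bp.

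Of 19974 coding genes, 11073 (55.4%) had a peak at a gene end in both lists, 1262 were treated-only, 11 were untreated-only and 7628 had none. In lists of equal length 653 were treated-only and 99 untreated-only. The 1262 treated-only genes of the main setting were 14.2% (13.5 to 14.9) of the 8890 genes with no untreated peak at their ends. For 937 of them the strongest treated peak was isolated, and 341 had an untreated peak elsewhere inside the gene. The 15 treated-only genes with the highest fold, up to 57.1, included LRRC27, PBX3, KMT5B, NUP210L, PNPLA8, RBMS2, CHD4, WNK4, CSF3R, WEE1, SNU13, ANAPC5, TCEAL4 and BABAM2. In all 15 the treated peak overlapped an untreated peak that did not reach into the 1 kb window. Of these genes 12, among them the chromatin remodeller CHD4 and the cell cycle kinase WEE1, held an untreated peak inside the gene and were thus marked in both libraries. The peaks at NUP210L, WNK4 and CSF3R lay outside the gene and touched further coding genes. Those at LRRC27 and BABAM2 touched another coding gene too.

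Isolated new peaks with high summits were few. SPHK1, which makes sphingosine 1-phosphate, had a treated peak at chromosome 17, 76383581 to 76383890, with a summit of 36 reads (25.2 to 49.8) and a fold of 24.3, and the nearest untreated peak lay 28.9 kb away. GPX4, the glutathione peroxidase that reduces lipid hydroperoxides, had one at chromosome 19, 1103310 to 1103750, with 35 reads (24.4 to 48.7), 8.33 kb from the nearest untreated peak. WFS1, a membrane protein of the endoplasmic reticulum, had 29 reads (19.4 to 41.6) at chromosome 4, 6270486 to 6270935. A peak of 25 reads (16.2 to 36.9) at chromosome 17, 42287758 to 42288220, touched the ends of STAT5A and STAT5B, which encode cytokine-activated transcription factors, and STAT5B held an untreated peak inside the gene. DHRS4L2 (27 reads), FKBP9 (26 reads), BEX2 (26 reads), L3MBTL1 (27 reads) and the neighbours LRRC43 and B3GNT4 (1 peak of 28 reads) were also among the 12 isolated treated-only genes with at least 25 reads, a set chosen after their values were seen. None of the 12 reached 37 reads, the minimum when the 95th percentile of the summit ratio takes the place of its median. DHRS4L2 has close relatives in the same cluster and its reads are uncertain, and its peak touched another coding gene.

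**Figure D3:**
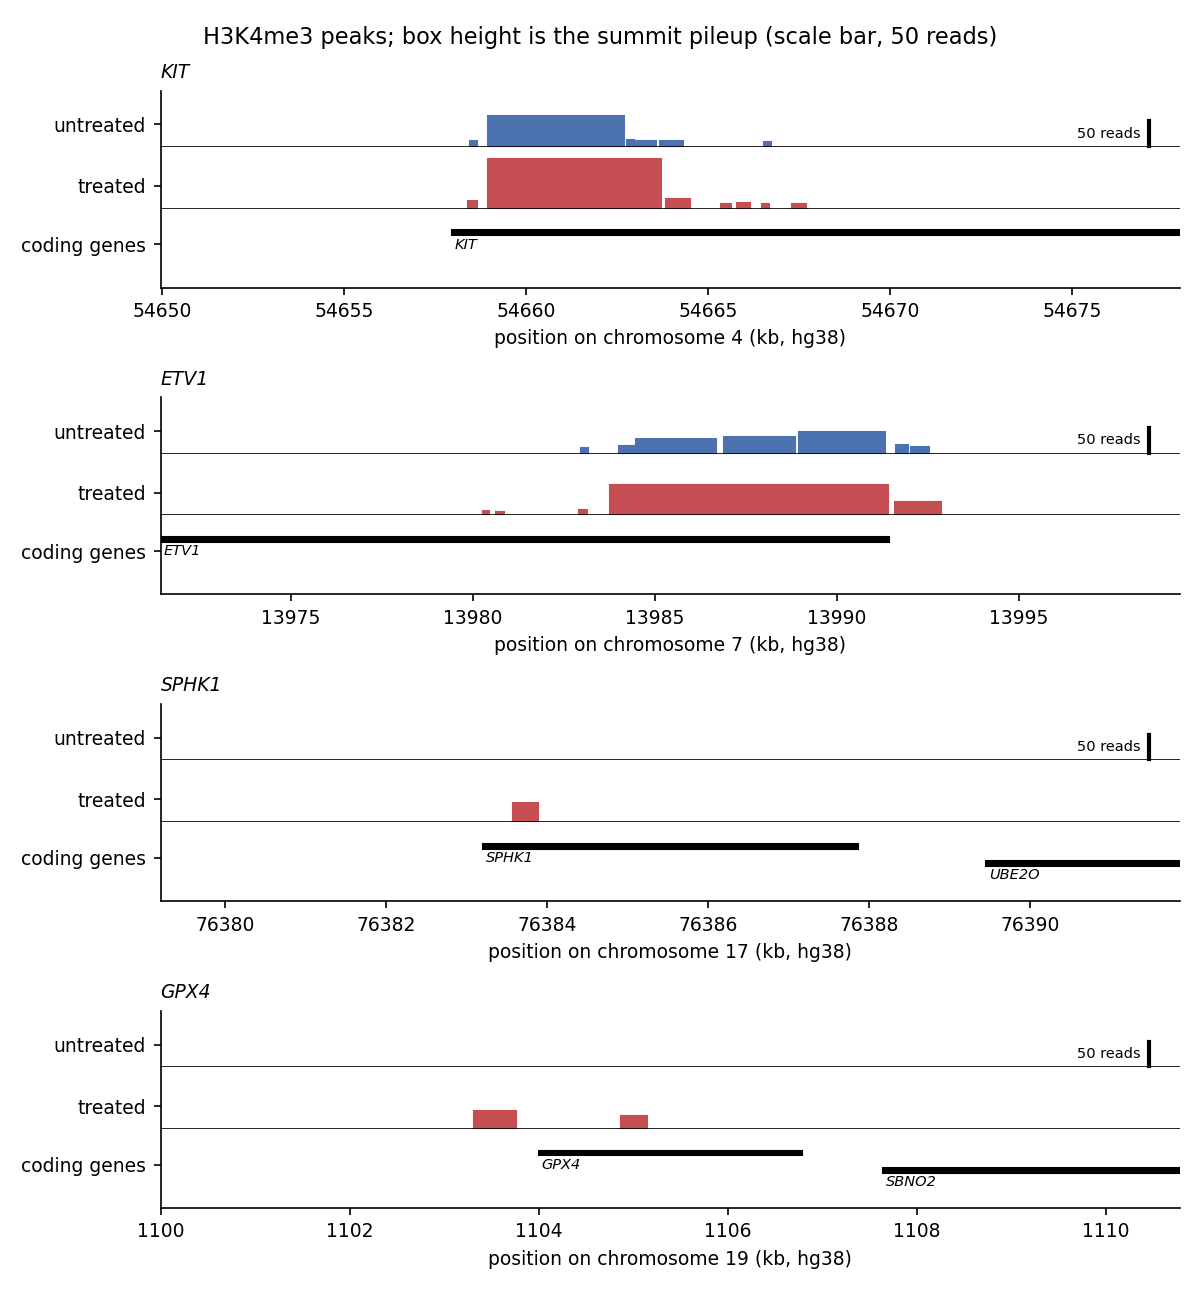
H3K4me3 peaks at KIT, ETV1, SPHK1 and GPX4 (x axis, position in kb on hg38), untreated above treated, each drawn to scale from start to end with a height equal to its summit pileup in reads, above the annotated extent of the coding genes. KIT and ETV1 were marked in both libraries, with summits of 61 and 98 reads at KIT and of 41 and 60 reads at ETV1, untreated and treated, while SPHK1 and GPX4 had treated peaks only.

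The genes of GIST and its lineage were marked before treatment and stayed marked. Of 20 listed genes, 17 had a peak at a gene end in both lists, 2 were treated-only and 1 had none. The 85.0% marked in the untreated library stood at the 99.7th percentile of random lists of coding genes. The percentiles of the housekeeping, chromatin enzyme, ZNF, ribosomal protein and histone lists were higher. Percentiles depend on list size: the larger ZNF and histone lists had lower marked shares, 80.1% and 76.2%. KIT, the receptor tyrosine kinase that drives most of these tumours, had a summit of 61 reads (46.7 to 78.4) untreated and 98 (79.6 to 119) treated. PDGFRA, the related receptor, had 58 and 89 reads, and ETV1, a transcription factor of the lineage, 41 (29.4 to 55.6) and 60 (45.8 to 77.2). ANO1, the chloride channel used as a diagnostic marker, had no peak at its annotated ends but was marked inside the gene in both lists, with a highest summit of 25 reads untreated and 42 treated. The treated-only members were IGF1R with 14 reads and FOXF2 with 10. IGF1R also held untreated peaks inside the gene. The treated to untreated ratios at KIT, PDGFRA and ETV1 lay below the median ratio of 1.70 over shared peaks with untreated summits of at least 20 reads. These genes had untreated summits above 40 reads, where the median ratio per read was lower, 2.32 against 2.44. The median of 1.70 is thus not a comparison with peaks of their height.

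Among immune genes, most interferon response genes were marked already, as were most coding genes, and some antigen presentation genes gained a weak peak. Of 53 interferon response and nucleic acid sensing genes, 33 (62.3%) had a peak in both lists, against 55.4% of all coding genes. Their share marked untreated stood at the 83.4th percentile of random lists of coding genes. Of the 20 eligible genes 5 (95% interval 11.2 to 46.9%) were treated-only, against 2.84 in random lists (percentile 90.1). They were GBP1 (14 reads), IRF7 (13), OASL (9), STING1 (10) and ZBP1, and all 5 peaks were isolated. The interferon list lay above the central 95% of random lists under 4 of 12 alternatives, all annotated genes among them. At −log10 q of at least 10 it had 9 of 28 eligible genes against 4.55. That cutoff also drops weak untreated peaks, which raised the eligible genes from 20 to 28. Genes added this way were marked before treatment, and the generally higher treated summits can make them treated-only. In antigen presentation 15 of 27 genes were marked in both lists and 4 of 12 eligible genes (33.3%, 13.8 to 60.9) were treated-only, against 1.71 in random lists (percentile 95.2). These included HLA-DMB (17 reads, chromosome 6, 32940616 to 32941082), HLA-B (10 reads, chromosome 6, 31357379 to 31357602) and CTSS (9 reads), and all 4 peaks were isolated. The antigen presentation list lay above the central 95% of random lists under 7 of 12 alternatives, which are not independent of one another. All annotated genes, most of which are not coding, are among them, with the same count of 4 against 0.631 in random lists. In peak lists of equal length the antigen presentation and interferon lists each had 2 treated-only genes. Of 34 cytokines and chemokines 6 were marked in both lists, and 2 of 28 eligible genes, CXCL3 (8 reads) and CXCL16 (6 reads), were treated-only (percentile 14.3). The CXCL16 peak touched another coding gene. Summits as low as those of these immune genes are those at which the treated library had many regions without an untreated peak.

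Genes often silenced by promoter methylation in tumours showed gains near the general share. Of 57 such genes, 27 had a peak in both lists, and 6 of 30 eligible genes (95% interval 9.51 to 37.3%) were treated-only, against 4.26 in random lists (percentile 81.2). DAPK1, a death-associated kinase, had a summit of 14 reads, RASSF2 of 13, SOCS3, a feedback inhibitor of cytokine signalling, of 12, and RASSF1 of 17. The RASSF1 peak lay beyond the low-coordinate end of the gene and touched another coding gene. The RASSF1 and SOCS3 peaks lay 512 and 933 bp from an untreated peak, and both genes held untreated peaks. DKK3 and CACNA1G were the remaining treated-only genes. Of 22 cell cycle inhibitors 17 were marked in both lists, and CDKN1C, with 8 reads at its low-coordinate end, was the only treated-only gene of 5 eligible (percentile 65.0). Of 31 imprinted genes 13 were marked in both lists, and L3MBTL1 (27 reads), RTL1 (14 reads) and CDKN1C were treated-only among 18 eligible (percentile 63.9). Among 41 chromatin enzymes, 36 were marked in both lists, and the DNA methyltransferase gene DNMT3A (17 reads, chromosome 2, 25342703 to 25343037) was the treated-only gene of 5 eligible (percentile 66.3). In the unfolded protein response CHAC1 (11 reads) and TRIB3 (11 reads) were treated-only among 5 eligible (percentile 91.3), and 18 of 23 genes were marked in both lists. The TRIB3 peak lay 1585 bp from an untreated peak, and TRIB3 held an untreated peak inside the gene. At −log10 q of at least 5 the list had 4 treated-only genes of 7 eligible (percentile 99.6). The rise from 5 to 7 eligible genes came from untreated peaks below that cutoff.

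The treated-only counts of genes of other tissues and of developmental regulators lay inside the central 95% of random lists in the main setting. Of 40 neuronal genes 6 were marked in both lists, and 8 of 34 eligible genes (23.5%) were treated-only, against 4.85 in random lists (percentile 92.9). With −log10 q of at least 10 this turned round, to 2 of 35 against 5.68 in random lists (percentile 3.72), and in lists of equal length it was 2 of 34 against 2.51 (percentile 41.0). GAD1, which makes the transmitter GABA, had 19 reads at chromosome 2, 170813150 to 170813578, SYP, a synaptic vesicle protein, 14 reads, and the secretory granule genes SCG3 and VGF 10 reads each. GAD1 and SYP held untreated peaks inside the gene, and the GAD1 peak lay 4085 bp from an untreated peak. The VGF peak touched another coding gene. In smooth muscle, 5 of 17 genes were marked in both lists and TPM2 (18 reads), SYNPO2 (12 reads) and the myosin heavy chain MYH11 (9 reads) were treated-only among 12 eligible (percentile 84.2). Of 120 developmental transcription factors 44 were marked in both lists and 15 of 76 eligible genes (19.7%) were treated-only (percentile 91.4), led by NKX3-2 (46 reads), PITX1 (23 reads), CDX2 (14 reads) and EN1 (14 reads). PITX1 held an untreated peak inside the gene, and its treated peak lay 1242 bp from an untreated one. The NKX3-2 peak overlapped an untreated peak outside the window, and in lists of equal length 5 of the 76 genes were treated-only, against 5.57 in random lists. Of 39 HOX genes 21 were marked in both lists, and HOXD11 (17 reads), HOXA4 (10 reads), HOXA10 (7 reads) and HOXD13 (7 reads) were treated-only among 18 eligible (percentile 82.9). The HOXA10 and HOXD13 peaks lay 2343 and 4895 bp from an untreated peak, and HOXD13 held one inside the gene. The HOXA10 peak touched further coding genes. Treated-only counts were 1 of 21 eligible epithelial genes (ESRP2, 10 reads, percentile 11.2) and 2 of 24 blood cell genes, CD4 with 14 reads and TYROBP with 8 (percentile 22.3). They were 1 of 12 endothelial genes (SOX18, 10 reads, percentile 31.4), 1 of 15 pluripotency genes (SALL4, 10 reads, percentile 22.5) and 1 of 24 genes of liver, pancreas and eye (APOA1, 9 reads at its low-coordinate end, percentile 7.85). The CD4 and TYROBP peaks each touched another coding gene, and the ESRP2, CD4 and SALL4 peaks lay 576, 402 and 185 bp from an untreated peak. The epithelial list fell below the central 95% of random lists under 4 of 12 alternatives, with 0 of 22 eligible genes (percentile 1.07) at −log10 q of at least 10, where the list of liver, pancreas and eye also had 0 (percentile 0.685).

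**Figure D4:**
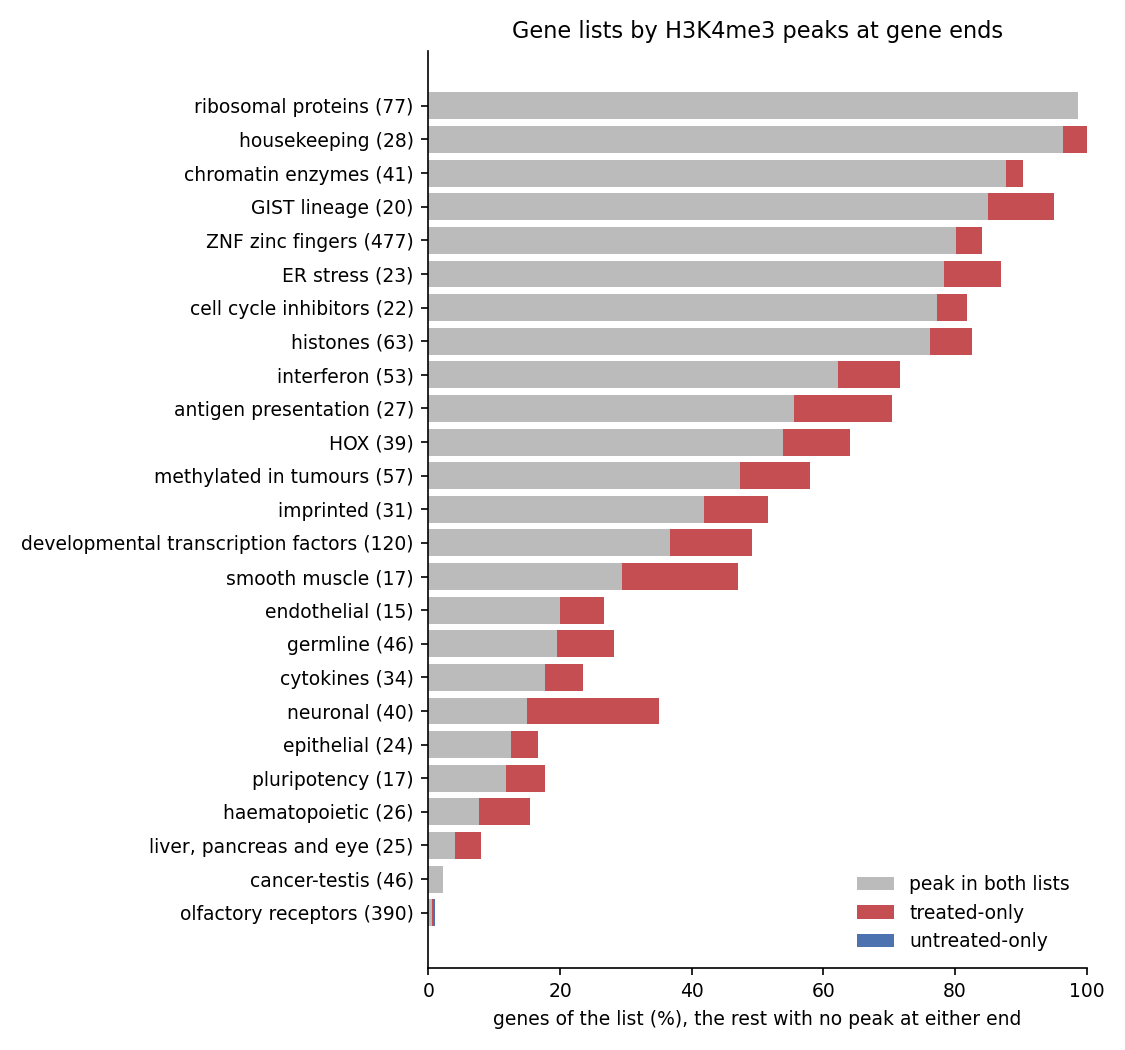
Share of the genes of each fixed list (y axis, number of coding genes in parentheses) with an H3K4me3 peak at a gene end in both lists (grey), in the treated list only (red) or in the untreated list only (blue), in percent of the list on the x axis. Ribosomal protein and housekeeping genes were nearly all marked in both lists, the neuronal list had 8 treated-only genes of 40, and the cancer-testis list had 0 of 46.

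No cancer-testis gene gained a peak. Of 46 listed genes, 1 had a peak in both lists, and 0 of the 45 eligible genes (95% interval 0 to 7.87%) were treated-only, against 6.38 in random lists (percentile 0.040). Olfactory receptors, silent outside the nose in most tissues, behaved alike: 1 of 387 eligible genes, OR52N2 with 7 reads, was treated-only, against 55.0 in random lists. These were the only lists of 25 outside the central 95% of random lists. The 1.25 that chance gives over 25 lists is only a guide. The housekeeping and ribosomal protein lists, with 1 eligible gene each, could not fall outside. Of 46 germ-cell genes 9 were marked in both lists, and MEI1 (15 reads), SYCP2 (13 reads), NANOS3 (15 reads) and TEX15 (8 reads), which act in meiosis or germ-cell development, were treated-only among 37 eligible (percentile 29.2). The MEI1 peak lay at the high-coordinate end, 158 bp from an untreated peak, and touched another coding gene, as did the SYCP2 peak. The TEX15 peak lay 851 bp from an untreated peak, and TEX15 held an untreated peak inside the gene. Of 477 ZNF zinc finger genes 382 were marked in both lists and 19 of 95 eligible genes (95% interval 13.2 to 29.1%) were treated-only (percentile 93.7), among them ZNF225 (46 reads, on a peak shared outside the window), ZNF502 (22 reads), ZNF239 (23 reads) and ZNF501 (16 reads). The ZNF list lay above the central 95% of random lists under 6 of 12 alternatives, all annotated genes among them. At −log10 q of at least 10 it had 39 of 125 eligible genes against 20.2. The rise from 95 to 125 eligible ZNF genes came from untreated peaks below that cutoff, so the added genes were marked before treatment. Of 63 core histone genes 48 were marked in both lists and H2AC14, H2BC14, H4C12 and H2BC6, with 7 to 13 reads, were treated-only among 15 eligible (percentile 90.0), of which 1 peak was isolated. H2AC14 and H2BC14 were both counted on the same peak. Of 77 ribosomal protein genes 76, and of 28 housekeeping genes 27, were marked in both lists. The treated-only housekeeping gene was GPI with 15 reads, and it held an untreated peak inside the gene.

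Peaks lost on treatment were few and weak in the main setting. The 11 untreated-only genes were 0.0551% of the coding genes, and 99.9% of the 11084 genes with an untreated peak kept one. Untreated-only genes numbered 99 in lists of equal length and 100 with summits in the window. CDK5R1, an activator of the kinase CDK5, had an untreated summit of 11 reads (5.49 to 19.7) at chromosome 17, 32487685 to 32487884. TRABD2B had 10 reads, CYP2F1, MYEOV, RAB15 and SEMA3B had 9 each, and BARX2 and SPNS2 had 8 each. SEMA3B had a treated peak elsewhere in the gene. OR5T3, with 6 reads, was the only untreated-only gene of a fixed list. Untreated-only peaks had a median summit of 8 reads and a median width of 173 bp, and 172 of the 329 lay within 1 kb of a treated peak. A further 139 lay more than 5 kb from any. Scaling by the summit ratio predicted that 5.15 untreated-only peaks would go uncalled in the treated library, far fewer than the 329 observed. This excess does not decide for a loss. The prediction holds ratio and background fixed, and the summits of these peaks lay near the lowest that were called. In lists of equal length the untreated-only peaks numbered 1303.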

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

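The test against the general rise in peak number was chosen after the result was seen, and the test on many-copy sequences was stated before it. Peaks on unplaced and unlocalised contigs, which the comparisons leave out, numbered 107 in the treated list (95% Poisson interval 87.7 to 129) and 35 in the untreated list (24.4 to 48.7), and they drew attention as a signal outside the main measurement that was higher than in the untreated library. They lay on 40 contigs, with at most 10 on any of them, a median summit of 10 reads, and 78 overlapped no untreated peak. The general rise in peak number argues against itself as the whole cause: scaled from the chromosomes it would give 48.2 treated contig peaks, below the observed interval. If collapsed many-copy sequence were the source, a raised local background should be more frequent there, yet it was found at 31.8% (23.7 to 41.1) of treated contig peaks against 41.5% (41.0 to 42.0) of chromosomal ones, lower by 9.71 percentage points (0.372 to 17.8). A response of these sequences to the drugs and the difference in enrichment between the immunoprecipitations stay open, because each group has 1 library.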

How the results depend on the processing

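Treated-only peaks and genes outnumbered untreated-only ones under every alternative that gave both counts, but the counts moved. Main counts were 13374 treated-only and 329 untreated-only peaks, and 1262 and 11 genes. With −log10 q of at least 10 in both lists, treated-only peaks were 8558, untreated-only peaks 60 and untreated-only genes 7. With that value at 5 or more for private peaks alone, they were 8392, 115 and 6. Lists of equal length gave 4357 and 1303 peaks and 653 and 99 genes, a consequence of removing the weakest treated peaks. Counting a peak within 1 kb as shared gave 8095 and 157, and merging peaks within 1 kb gave 6456 and 201. Untreated-only genes were 28 with a 500 bp window and 100 with summits in the window. All annotated genes gave 2339 and 30, since more genes were counted. Windows of 2 kb raised the share of peaks at gene ends to 81.6% untreated and 72.5% treated, and lists of equal length raised the treated share to 75.7%, above the untreated share of 73.9%, which turns that difference round. Among alternatives chosen after seeing the data, a distance above 5 kb left 6727 and 139 peaks, a summit of 25 reads or more left 231 treated-only peaks, and both conditions left 12 treated-only genes. Peaks tied to 1 coding gene gave 121 untreated-only genes, and leaving out genes with an untreated peak anywhere inside them left 921 treated-only genes. Where no cause is named, the cause was not tested. Over the gene lists, 181 of 248 counts stayed within 1.5 times the main count and 67 did not, leaving out all annotated genes and matched random lists, where each count equals the main one. The cancer-testis list stayed below the central 95% of random lists under 11 of 12 alternatives, with a highest percentile of 4.20, and the olfactory list under all 12. Antigen presentation ranged from the 86.1st to the 99.9th percentile, interferon response from 69.0 to 99.7 neuronal genes from 3.72 to 99.9 and ZNF genes from 66.7 to 100. GIST lineage and unfolded protein response genes lay above the central 95% under 4 alternatives each, housekeeping genes under 3 and chromatin enzymes under 1 (6 of 10 at −log10 q of at least 10), and cytokines below it under 1. With all annotated genes, most of which are not coding, smooth muscle, neuronal, HOX, developmental, tumour-methylated and histone genes lay above it too. Stricter cutoffs also drop weak untreated peaks, so genes marked before treatment became eligible. At −log10 q of at least 10 the eligible chromatin enzymes rose from 5 to 10 and the eligible ZNF genes from 95 to 125. Such genes can turn treated-only through the generally higher treated summits. Using the 5′ end of genes alone and matching on CpG content were not run, as strand and genome were not used here. Summits of under 10 reads limit what absence in the untreated library means. No paired analysis was possible because each group has 1 library.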

Other observations

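Genes of the GIST lineage list had wide H3K4me3 regions, a comparison made after the values were seen. In the untreated library the widest regions lay at MEIS2 (13620 bp, chromosome 15, 37094111 to 37107730) and MEIS1 (13278 bp, chromosome 2, 66432690 to 66445967), both homeobox transcription factors, at TBC1D19 and STIM2 (11122 bp, 1 region), at ETV1 (9585 bp) and at the long noncoding RNA MALAT1 (9439 bp). SPRY1 (9172 bp) and SPRY4 (9018 bp), feedback inhibitors of receptor tyrosine kinase signalling, followed. In the treated library 2 of the 3 widest regions lay in the repeated 5S ribosomal RNA genes of chromosome 1 (19829 and 18302 bp), with MEIS2 (18529 bp) between them. Of the GIST lineage list, ETV1, SPRY4, HAND2, PDE3A, DUSP6, FOXF1 and KIT ranked 4, 7, 11, 14, 17, 42 and 43 by width among 15697 untreated regions. The median over the 17 marked members was 5206 bp, against 1496 bp over all marked coding genes and above all 10000 random lists, whose central 95% ended at 1977 bp. Core histone genes (median 3446 bp), HOX genes (2528 bp) and ribosomal protein genes (1813 bp) also stood above the central 95% of random lists, while marked developmental transcription factors (708 bp), interferon genes (852 bp), cytokines (421 bp) and ZNF genes (1312 bp) stood below it. In the treated library the lineage genes (median 4982 bp), histone genes and HOX genes again stood above it, joined by housekeeping genes, cell cycle inhibitors, chromatin enzymes and the unfolded protein response. Interferon genes (1073 bp), developmental transcription factors, cytokines and ZNF genes again stood below it, joined by germ-cell, antigen presentation, neuronal and imprinted genes. Histone and HOX genes sit in clusters, where regions of neighbouring genes merge.

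Long noncoding and microRNA genes gained peaks less often than coding genes. Of 14899 long noncoding RNA genes with no untreated peak at their ends 679 (4.56%, 4.23 to 4.90) had a treated peak there, as did 55 of 1711 microRNA genes (3.21%, 2.48 to 4.16), against 14.2% of coding genes. For 292 long noncoding genes and 4 microRNA genes an isolated treated-only peak lay away from any coding gene. Genes with symbols of their own among the highest folds, chosen after their values were seen, were EP300-AS1 (29 reads, chromosome 22, 41197812 to 41198179), C3orf36 (25 reads), LINC01703 (24 reads) and THBS2-AS1 (24 reads).

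The test of read depth and the comparison of regions with 25 reads or more were chosen after the result was seen, both tests of a general rise in enrichment were stated before theirs, and the reading of the weak regions as undecided was adopted only after their value was seen. More peaks were found in the treated list, 36769 against 26682 on the chromosomes, and deeper sequencing is argued against, as the treated library held 0.695 of the untreated reads. For a higher enrichment at every marked site, from the drugs or from the immunoprecipitation, the strong regions met the bound of 1% stated before. Of 8442 regions with at least 37 reads, 0.0711% (0.0326 to 0.155) had no untreated peak within 5 kb. That bound was loose: at 40 reads or more 4 regions were new, where the median ratio and 7 reads predicted 0.00883. Meeting it therefore does not decide. For weak regions the same scaling predicted 0.451 of the 5265 observed new regions with a lowest callable summit of 5 reads. That is below the bound of 0.5 stated before and taken alone counts against higher enrichment. With 7 reads, the 5th percentile of the untreated summits, it predicted 0.782 of them. By summit, 7 reads predicted 2750 of 2994 new regions at up to 9 reads and 1123 of 1649 at 10 to 14. At 15 to 19 reads they predicted only 209 of 490, and at 20 to 24 only 34.4 of 132, both below that bound. Over all weak regions, higher enrichment and site-specific gains cannot be told apart. With 25 reads or more 57 regions were new where the median ratio and 7 reads predicted 5.47. In the other direction scaling predicted 5.15 untreated-only peaks uncalled in the treated library, where 329 were observed, and no bound was stated for it. None of these excesses decides, since the predictions hold ratio and background fixed. A drug response stays untested with 1 library per group.

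The test on near-identical copies was chosen after the result was seen, and the test on the X chromosome before it. Cancer-testis genes gained 0 peaks among 45 eligible genes where random lists gave 6.38, although this class is known for silencing by DNA methylation. Location on the X chromosome is argued against: other X-linked genes gained peaks at 0.992 times the autosomal share (0.783 to 1.26). Reads lost between near-identical copies as the whole cause would leave gains at the general share among the 19 eligible members without such a relative, of which 0 gained a peak. At the general share, chance gives this with probability 0.0545, too often for so few members to decide for or against that explanation. Promoter sequence stays open and was not tested, as CpG content needs a genome. Of 112 gene families searched by symbol after the values were seen, 6 fell below the 0.5th percentile of random lists: keratin-associated proteins (0 of 94), keratins (0 of 52), beta-defensins (0 of 39), GPR receptors (1 of 56), olfactory receptors (1 of 389) and loci without a symbol of their own (35 of 491), against 13.4, 7.38, 5.55, 7.93, 55.3 and 69.6 in random lists.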
